A study of Homo sapiens with 3 samples.

How the data were processed

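RNA was measured by sequencing in 3 libraries of MCF10Ca1h, an established human breast cancer cell line, with 1 library for each of 3 groups. The untreated library is called NT, and the libraries of cells given the PADI4 inhibitor GSK484 or the control compound for 72 h are called GSK484 and CON. Per the labels' protocols, RNA was taken up in TRIzol, libraries were made with a stranded total RNA kit, and reads were paired-end of 125 bp. The labels give no dose and give the untreated library no time. Per the labels' treatment text the control compound is GSK107, while the deposited table of that library carries the name GSK106 for it, so it is called the control compound throughout.

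The authors deposited 1 gene table per library, each with 56632 Ensembl gene IDs. The deposited expected counts are estimates of the reads belonging to each gene, not normalized and not always whole, per the file headers. The deposited TPM values are transcript abundances that account for effective length and are scaled to the same total in every library, per the file headers. Per the submitters' processing notes, RSEM and the hg19 build were used. The RSEM version, the aligner, its settings, the gene annotation release and the strand setting of the counting are not given in the sources used here. Because that strand setting is not known, antisense genes are treated as uncertain. FPKM values, held in the same tables, were not used.

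The total expected count was 70555229 in NT, 92980847 in CON and 77220120 in GSK484. Expected counts were scaled to library size as CPM, with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.01, 0.98 and 1.01 in the same order. A log2 fold used a prior count of 0.5 scaled to library size. Its 95% interval was the exact conditional binomial (Clopper-Pearson) interval on expected counts rounded to whole numbers. With 1 library per group there are no replicates, so no test between conditions was possible, and every interval or floor covers counting error only. PCR copies were not separable from molecules. A count of 0 allows up to 3 counts, which is 0.042 CPM in NT, 0.033 in CON and 0.038 in GSK484. A fold against this floor takes the other library's count as exact, and the interval bound given beside it also covers that count's error.

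Before the data were examined, a rule of size was fixed in place of a test. A gene counted as higher or lower where its fold was at least 2, its counting interval excluded no difference and the larger of both CPM values was at least 1. The comparisons were GSK484 against CON, GSK484 against NT and CON against NT. Genes named in the text had a symbol and an effective length of at least 200 in every library. They were the 12 higher and 12 lower genes for GSK484 against CON, ranked by the interval bound nearest to no difference. Next came up to 6 higher and 6 lower for GSK484 against both other libraries, and the 6 higher and 6 lower of each other comparison. All PADI family members, POU5F1, NANOG, SOX2, KLF4, MYC, CD44, CD24, ALDH1A1 and ALDH1A3 were also included, whatever their value. From each gene list, up to 4 members with the largest absolute fold for GSK484 against CON, beyond counting error, completed the set. Further genes named in the text are said to have been chosen after their values were seen.

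The 36 gene lists, with 728 entries, were also written before the data were examined. A member was measured where its CPM reached 1 in at least 1 library. Each list's median log2 fold was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile below 2.5, or as far toward the upper end, is called extreme, as a description of these libraries. Genes of a list vary together, so such percentiles are no test of a condition. Lists with fewer than 3 measured members got no percentile.

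Symbols were matched by gene ID from a gene name table and GENCODE release 29, used only for names, gene types and GC content, since it belongs to another build than the deposited tables. No coordinates were used. A symbol was found for 39173 of the 56632 IDs, and for 12616 of the 13312 genes measured in at least 1 library. The 17459 IDs with no symbol took about 1.0% to 1.1% of each library's counts. The 26 unmatched list entries and rule genes, among them CD24 and PADI6, were not analysed here.

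Some checks were chosen after the data were seen. To set the number of lists extreme against both CON and NT beside a value without list structure, the same random lists were read in both comparisons. A smooth trend of log2 fold on GC content and effective length was fitted with natural splines to 8874 protein-coding genes of at least 10 CPM and removed. GC content, from the longest annotated transcript, was known for 97.2% of measured genes. A gene of unknown GC content could not be counted as higher or lower by the rule once the trend was removed. Genes whose expected counts were whole within 0.005 in all 3 libraries were also taken alone, since a fraction shows that reads were divided between genes, while a whole count does not exclude it. They made up 61.0% of measured genes. Other settings fixed before the data were examined were library totals without TMM, DESeq2 1.42.0 size factors, totals without short, mitochondrial and histone genes, and the deposited TPM with a pseudocount of 0.5. They also held a prior count of 5, other CPM minimums, fold minimums of 1.5 and 4, a stricter interval bound, and a minimum effective length.

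On simulated libraries with no replicate spread, the rule recovered 100% of 66 genes changed 2.5-fold and 100% of 63 genes changed 4-fold for GSK484 against CON. It called 0 of 71 genes changed 1.5-fold, which lie below its minimum, and 0 of 12878 unchanged genes, with an interval coverage of 95.1%. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.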

Results

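The data were gene-level RNA-seq values of 3 libraries of MCF10Ca1h cells, a tumour-forming line of the MCF10 breast epithelial series. One library came from untreated cells (NT), 1 from cells given GSK484 for 72 h and 1 from cells given a control compound for 72 h (CON). GSK484 inhibits PADI4, an enzyme that turns arginine residues of histones and other proteins into citrulline. The study's title places the work in the question of how PADI4 affects breast cancer stem cells. Total expected counts were 70555229 in NT, 92980847 in CON and 77220120 in GSK484, and 12989, 13026 and 13010 genes reached 1 CPM. There were no replicates, so all differences below are between single libraries, without a check against replicate spread.

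GSK484 against CON sets the inhibitor against the control compound at the same time point, with the doses not given. Among genes with whole expected counts in all 3 libraries, LOXL4 (ENSG00000138131), a lysyl oxidase family enzyme, was 2.12-fold lower in the GSK484 library, at 2.10 CPM against 4.47 (log2 fold -1.09, counting interval -1.36 to -0.82). NDUFA4L2 (ENSG00000185633), a hypoxia-induced mitochondrial protein gene, was 2.28-fold lower (log2 fold -1.19, interval -1.60 to -0.80). CXCL17, a mucosal chemokine gene, was 2.35-fold lower (log2 fold -1.23, interval -1.73 to -0.78). IFIT2, an interferon-induced gene, was 2.01-fold lower, at 2.04 CPM against 4.10 (interval of the log2 fold -1.28 to -0.74). That fold lies so close to the minimum of 2 that its call depends on the scaling. MARCHF4 (ENSG00000144583), a membrane-associated ubiquitin ligase gene, was 2.31-fold higher, at 3.32 CPM against 1.44 (log2 fold 1.21, interval 0.90 to 1.53). NEGR1, a neuronal cell adhesion gene, was 2.62-fold higher (log2 fold 1.39, interval 0.93 to 1.88). Against NT, NEGR1 (0.37, interval -0.03 to 0.78) and CXCL17 (-0.40, interval -0.96 to 0.15) were within counting error, while MARCHF4 was higher (0.76, interval 0.46 to 1.07). CON was lower than NT for NEGR1 (log2 fold -1.02, or -0.56 with the GC and length trend removed) and higher for CXCL17 (0.83). The deposited TPM of NEGR1 differed from this, at 0.4 in NT, 0.39 in CON and 0.76 in GSK484.

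By the rule of size, 26 genes were higher and 36 lower in GSK484 than in CON, of 13199 genes compared. Scaling to total counts without TMM gave 37 higher and 29 lower. Of these 62 genes, 13 had whole counts in all 3 libraries, 6 higher and 7 lower. PRR15L (log2 fold -1.05) and the integrin gene ITGB3 (log2 fold -1.02) were among the lower ones. So was PIK3IP1 (log2 fold -1.06), an inhibitor of PI3 kinase signalling outside the preset naming rule and chosen after its values were seen. Against NT, PIK3IP1 was within counting error (-0.54, interval -1.16 to 0.06). The larger folds belonged to genes whose reads were divided with other genes, and their values are uncertain. PHLDA1-AS1, antisense to PHLDA1, was at 4.85 CPM in GSK484 and 0.68 in CON (log2 fold 2.82). LYSMD3 was at 6.67 CPM in GSK484, 1.23 in CON and 6.96 in NT (log2 fold 2.43 against CON). MYZAP was higher (log2 fold 1.30) while the readthrough gene GCOM1, which spans it, was lower (log2 fold -1.53). CXCR5, a B cell chemokine receptor gene, was at 13.5 CPM in CON with a count that rounds to 0 in GSK484, at least 350.1-fold lower against a floor of 3 counts (interval bound of the log2 fold -8.15). It had a count of 0 in NT. The pseudogene ZBTB45P1 had a count of 0 in CON, and GSK484 was at least 35.8-fold higher against the floor (bound 4.84). GTF2IRD1P1, another pseudogene, had a count of 0 in GSK484, at least 27.8-fold lower against the floor (bound -4.48). The remaining named genes with divided reads had log2 folds of 1.12 to 1.30 for PTGES3P1, ICAM4-AS1, POLR2J2, CTAGE8 and TUBB1, and of -1.79 to -1.01 for ZNF593OS, SULT1A3, RPL32P29 and PCDHGB7. CCDC180 was at 1.27 CPM in GSK484 and 0.63 in CON. Most expressed genes differed little. Over 3973 genes of at least 50 CPM the median absolute log2 fold was 0.08.

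**Figure D1:**
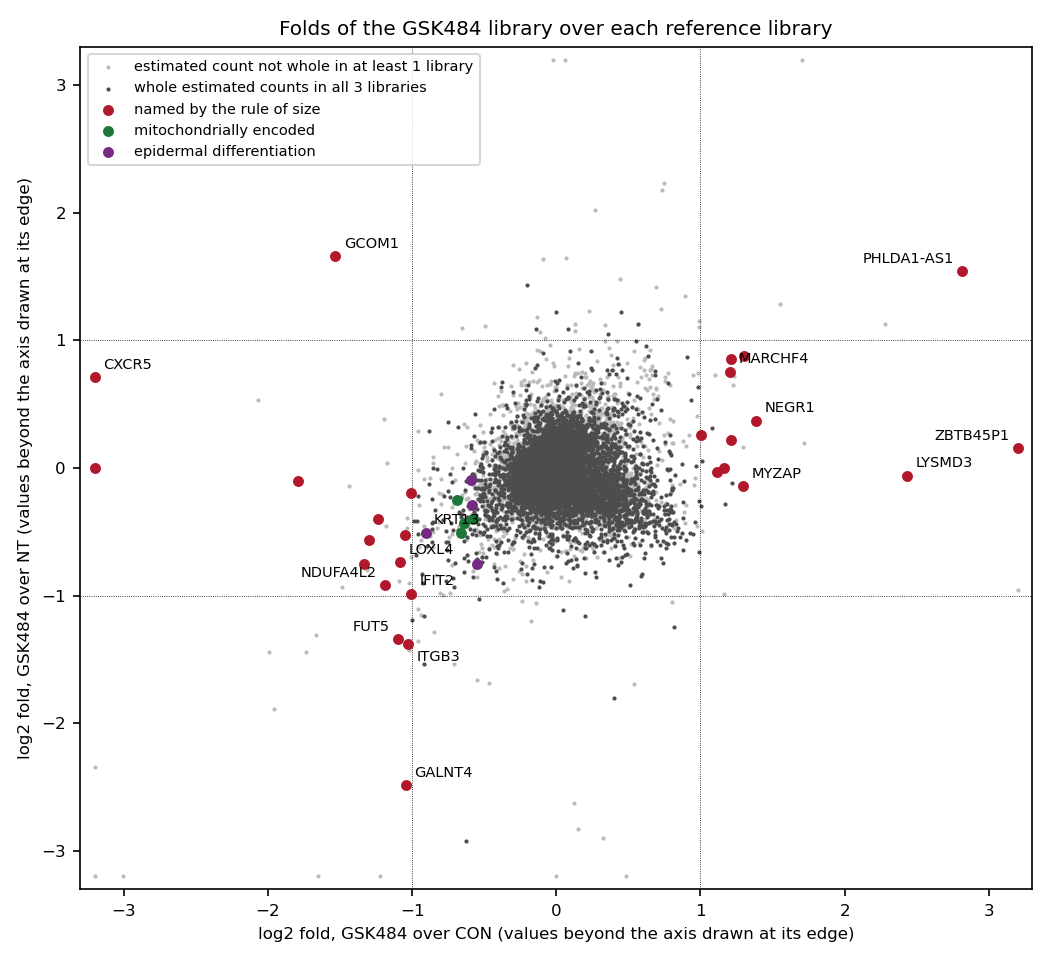
Each point is a gene measured in these libraries, with its log2 fold of GSK484 over CON on the horizontal axis and of GSK484 over NT on the vertical axis, both axes clipped at their edges. Dark points have whole counts in all 3 libraries, and coloured points include the genes named by the rule of size. Of the mitochondrial and epidermal lists, only up to 4 members each are coloured, those named for the largest absolute folds of GSK484 over CON. ITGB3 lies lower on both axes, at -1.02 and -1.38, while LYSMD3 lies at 2.43 and -0.06.

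Of 32 gene lists with at least 3 measured members, 10 were extreme on the low side and 4 on the high side for GSK484 against CON. All 13 mitochondrially encoded genes, which code for respiratory chain subunits, were lower beyond counting error. Their median log2 fold was -0.54, or 1.46-fold lower, below all 10000 random lists (percentile 0). MT-ND1 had a log2 fold of -0.69, MT-ND4 of -0.66 and MT-CYB, with whole counts, of -0.58. Mitochondrial genes took 4.03% of counts in GSK484, 5.33% in CON and 4.78% in NT. Of 12 measured epidermal differentiation genes, which mark maturing squamous cells, 9 were lower and 0 higher beyond counting error, with a median log2 fold of -0.24 (percentile 0.03). KRT13, a keratin of non-cornified squamous epithelium, had a log2 fold of -0.91 (interval -1.14 to -0.68), and KRT4, its keratin partner, of -0.58. SPRR1A (-0.59) and SPRR2D (-0.55), cornified envelope genes, carried divided reads.

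Hypoxia and glycolysis genes had a median log2 fold of -0.11 (percentile 0.11), with 15 of 25 lower and 1 higher beyond counting error. CA9, a hypoxia-induced carbonic anhydrase gene, had a log2 fold of -0.58, EGLN3, an oxygen-sensing prolyl hydroxylase gene, of -0.40, and ADM of -0.32. NRF2 targets, genes of the oxidative stress response, had a median of -0.10 (percentile 1.43), with 16 of 22 lower. The aldo-keto reductase genes AKR1C1 (-0.50), AKR1C2 (-0.40) and AKR1C3 (-0.38), all with divided reads, were the lowest among them. SLC7A11, a cystine transporter gene, was higher at 0.62, or 0.16 with the GC and length trend removed. With the deposited TPM the NRF2 median was 0.0056, where the median of all measured genes was 0.09. Aryl hydrocarbon receptor targets had a median of -0.20 (percentile 0.17), with CYP1B1 at -0.56 and NFE2L2 at 0.39, over 6 measured genes. Epithelial and luminal genes had a median of -0.09 (percentile 1.94), with ELF3, an epithelial transcription factor gene, at -0.61, KRT19 at -0.44 and FOXA1 at -0.28. Immediate early genes had a median of -0.08 (percentile 2.2), with EGR2 at -0.92, ATF3 at -0.61 and DUSP1 at -0.48, and a median of 0.041 with the deposited TPM, below that of all measured genes.

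PADI4 (ENSG00000159339) itself lay below the CPM minimum of the rule, at 0.60 CPM in GSK484, 0.68 in CON and 0.66 in NT, and a difference was not detectable at this depth (log2 fold against CON -0.17, interval -0.75 to 0.40). Its deposited TPM had another order, at 0.70 in GSK484, 0.51 in CON and 0.37 in NT. PADI2 had a log2 fold of -0.32 against CON, PADI1 of -0.20 and PADI3 of -0.19. The PADI family median over these 3 genes was -0.20 (percentile 1.06), and against NT it was -0.02 (percentile 42.6). Breast stem cell markers had a median log2 fold of 0.14 against CON (percentile 99.8), with 7 of 15 higher, 2 lower and 6 within counting error. With the GC and length trend removed the median was 0.05, at percentile 87.0. The largest fold of the list was that of ITGB3, which was lower (-1.02). SNAI2, a transcription factor gene of mammary basal cells, had a log2 fold of 0.42 and BCL11A of 0.41, while CD44, a hyaluronan receptor gene used to sort breast cancer stem cells, had 0.15. ALDH1A1 was within counting error (-0.13, interval -0.44 to 0.18), and ALDH1A3, whose reads were divided, was at -0.05. Pluripotency factors had a median of -0.13 (percentile 9.56) over 6 measured genes, with POU5F1 at -0.39, KLF4 at -0.20 and MYC at -0.11. Under TPM, ALDH1A3 (0.04) and MYC (0.0024) were above 0 but below the median of 0.09 of all measured genes. POU5F1 reads were divided with other genes, and its deposited TPM differed little, at 1.61 in GSK484 and 1.64 in CON. NANOG had a count of 0 in all 3 libraries, and SOX2 stayed at 0.084 CPM or less.

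Mitosis genes had a median log2 fold of 0.09 against CON (percentile 99.99), with MKI67, a proliferation marker, at 0.65 and the kinetochore genes CENPE at 0.88, or 0.43 with the GC and length trend removed, and CENPF at 0.69. Against NT their median was -0.10 (percentile 0.02), or -0.03 (percentile 16.3) with the trend removed. Basal keratins and basal epithelial genes had a median of 0.10 (percentile 99.99), with 13 of 20 higher and 4 lower. DST, a hemidesmosome linker gene, was at 0.80 and KRT6A, with divided reads, at 0.45. The basal and stress keratin genes KRT14 (-0.31), KRT15 (-0.26) and KRT16 (-0.30), chosen after their values were seen, were lower, KRT14 and KRT16 with divided reads. Against NT the basal median was 0.03 (percentile 60.85). Heat shock genes had a median of 0.08 (percentile 99.7), with 8 of 14 higher and 4 lower, HSP90AA1 at 0.63 and HSPH1 at 0.54. Against NT their median was -0.04 (percentile 3.21), with 4 higher and 6 lower, HSP90AA1 at -0.09 and HSPH1 at -0.08. Removing the GC and length trend gave a median against NT of -0.03 (percentile 20.9), with HSP90AA1 at -0.01 and HSPH1 at 0.07. Cytosolic ribosomal protein genes had a median of -0.14 (percentile 0), with 34 of 35 lower, and nuclear respiratory chain genes of -0.11 (percentile 0), with 27 of 28 lower. In the CON library, genes in the lowest sixth of GC content were lower than in NT, with a median log2 fold of -0.36, and GSK484 lay between the other libraries. With the GC and length trend removed, the ribosomal median was 0.0063 and the nuclear respiratory chain median was -0.00, while mitosis genes kept a median of 0.08 (percentile 99.97), heat shock genes 0.09 and basal genes 0.07. MT-ND1, MT-ND4, CA9, NFE2L2, ELF3 and HSP90AA1 also carried divided reads.

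The other lists lay inside the central range of random lists for GSK484 against CON. Their medians were -0.03 for p53 targets, DNA replication genes and interferon-stimulated genes, -0.05 for antigen presentation genes, 0.03 for inflammatory NF-kB genes and -0.01 for cholesterol synthesis genes. They were -0.02 for fatty acid synthesis genes, -0.07 for ATF4 and amino acid response genes, 0.02 for endoplasmic reticulum chaperone genes, 0.06 for mesenchymal and EMT factors and 0.06 for TGF-beta targets. Values of 0.03 for YAP and TEAD targets, -0.02 for WNT targets, -0.11 for Notch targets and 0.01 for glucocorticoid targets completed the signalling lists. With the GC and length trend removed, the ATF4 list became extreme on the low side (-0.06, percentile 2.42). Named genes inside these lists lay on both sides. LCN2, an iron-binding defence protein gene, had a log2 fold of -0.63, GDF15, a stress-induced secreted factor, of -0.54, IGFBP3 of -0.54, and ID2, a TGF-beta family target, of -0.68. The deposited TPM of ID2 differed less, at 3.56 in GSK484 and 3.81 in CON. DNAJC3, a chaperone gene, was at 0.55 and the cytokine gene IL1A at 0.46. Against NT, DNAJC3 (-0.06) and IL1A (-0.04) were within counting error. LCN2 (-0.17) and GDF15 (-0.10) were less far below NT than below CON, while IGFBP3 was at -0.40 and ID2 at -0.48. Of the interferon-stimulated genes, SAMD9 (0.61, or 0.21 with the trend removed) and IFIT3 (0.48) were higher, while IFI6 (-0.62) and IFIT2 (2.01-fold) were lower. Against NT, IFIT3 was within counting error (-0.10, interval -0.27 to 0.07). Markers of other cell types were sparse. Neutrophil and leukocyte markers had 4 of 18 genes measured (median 0.05) and fibroblast markers 3 of 12 (median 0.16). Endothelial markers were represented by CDH5 (-0.74), and adipocyte and erythroid markers by FABP4 (-0.41). Apart from cell type markers, replication-dependent histone genes were represented by H1-2 (-0.25) alone, with only 10 of 29 list entries matched to a gene ID. Metallothionein genes were represented by MT2A (0.37) and MT1X (0.01).

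**Figure D2:**
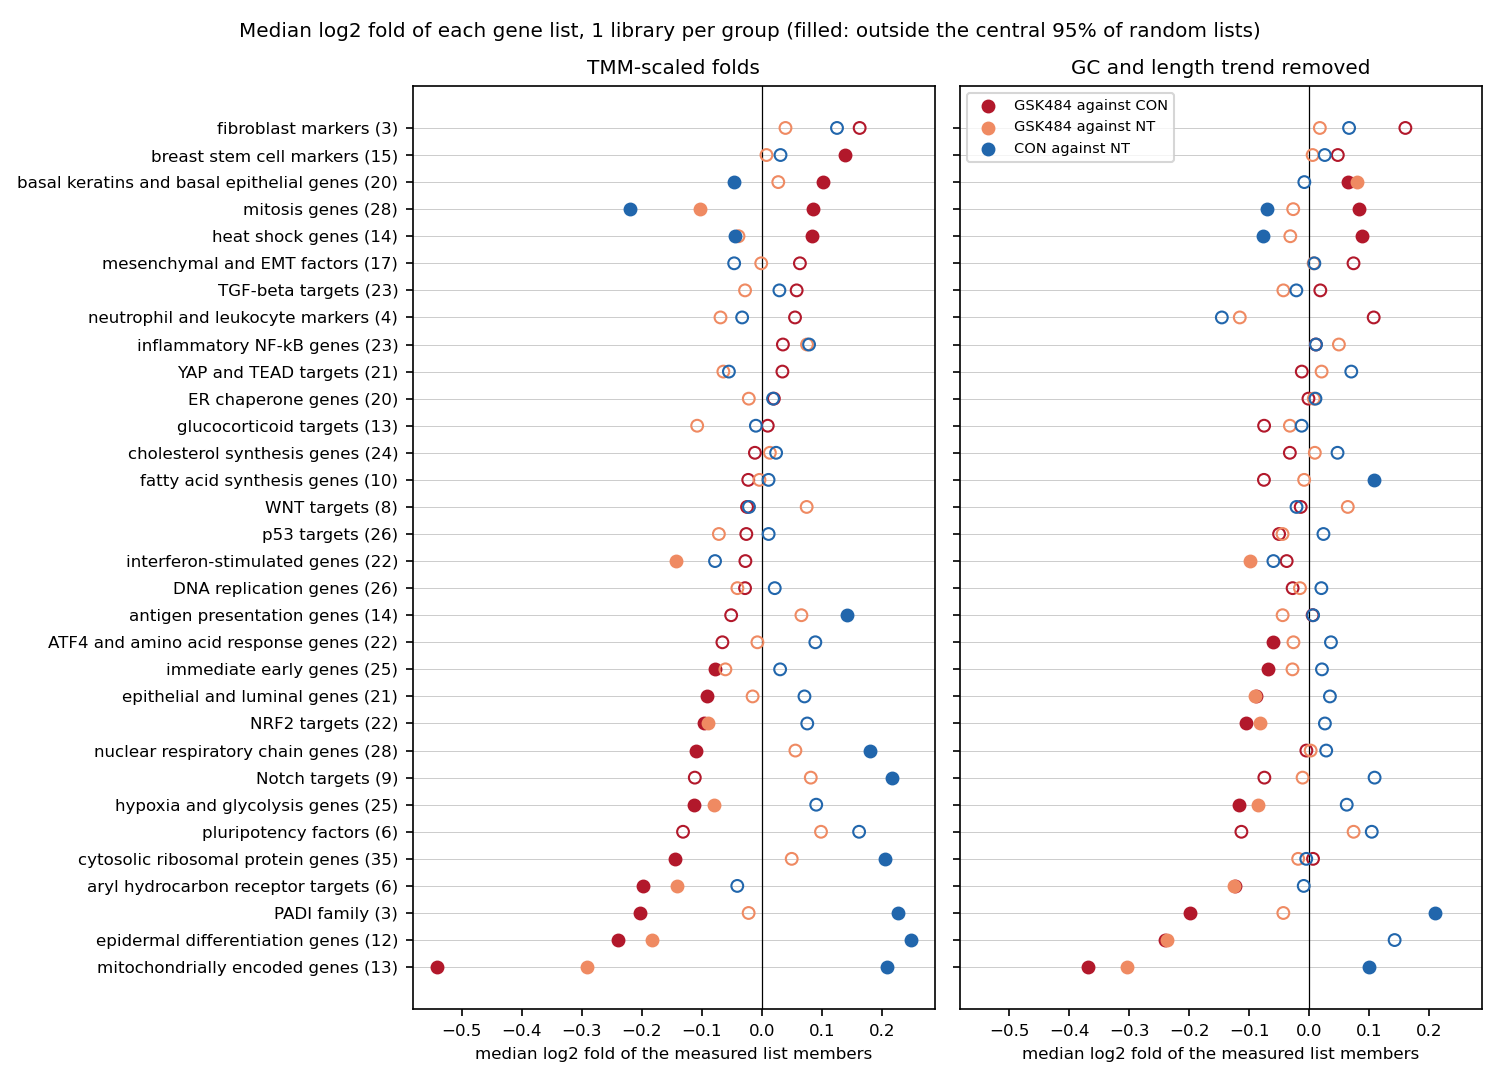
Each row is a gene list with its number of measured genes, and each point is the median log2 fold in 1 of the 3 comparisons, as scaled (left) and with the GC and length trend removed (right). Filled points lie outside the central 95% of 10000 random lists. Among these lists of at least 3 measured genes, the mitochondrially encoded genes lie lowest, at -0.54 for GSK484 against CON and -0.29 for GSK484 against NT.

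GSK484 against NT sets the inhibitor against untreated cells, whose time in culture the labels leave open. ITGB3, the integrin beta 3 gene, was lower in GSK484 than in NT (0.72 CPM against 1.88, log2 fold -1.38, interval -1.86 to -0.93) as well as lower than in CON. POMK, a kinase gene of dystroglycan glycosylation, was at 0.22 CPM in GSK484 and 1.70 in NT (log2 fold -2.93), and at 0.34 in CON. EGR2, an immediate early transcription factor gene, had a log2 fold of -1.16, while IFIT2 (-0.98), NDUFA4L2 (-0.92) and LOXL4 (-0.74) stayed short of the rule. The mitochondrially encoded genes had a median log2 fold of -0.29 (percentile 0), with 10 of 13 lower and 2 higher beyond counting error, and MT-CYB at -0.40. Epidermal differentiation genes had a median of -0.18 (percentile 1.75), with KRT13 at -0.51.

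By the rule of size, 34 genes were higher and 37 lower in GSK484 than in NT, of 13209. Of these, 16 had whole counts, 6 higher and 10 lower. Genes with divided reads included POC1B-GALNT4 (log2 fold 2.24) and GALNT4 (-2.48), which overlap and had opposite signs, and ASB16-AS1 (2.18), PVRIG2P (1.65), JMJD7 (1.64), SEPTIN7P13 (-2.83), PCDHAC1 (-1.68) and PCDHA7 (-1.53). ANKRD36BP1, a pseudogene with whole counts, was at -1.80. Hypoxia and glycolysis genes had a median of -0.08 (percentile 1.44), NRF2 targets of -0.09 (percentile 0.04), and aryl hydrocarbon receptor targets of -0.14 (percentile 2.35), with all 6 lower beyond counting error and CYP1B1 at -0.72. Interferon-stimulated genes had a median of -0.14 (percentile 1.79), with SAMD9 at -0.71, or -0.40 with the trend removed. Of 32 lists, 7 were extreme on the low side and 0 on the high side. Epithelial and luminal genes had a median of -0.02 (percentile 20.9), which was -0.09 with the trend removed, an extreme value. Basal genes then became extreme on the high side, at 0.08 (percentile 99.98). Immediate early genes had a median of -0.06 (percentile 3.16), and breast stem cell markers of 0.01 (percentile 41.2), while pluripotency factors were at 0.10 (percentile 80.5). Genes in the lowest sixth of GC content had a median log2 fold of -0.17.

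Against both other libraries, 4 genes were higher and 7 lower in GSK484, where independent lists of these sizes would share 0.07 and 0.10 and simulated libraries with no differences shared 0 and 0. Both comparisons use the same GSK484 library, so anything particular to that library enters both, for genes and lists alike. PHLDA1-AS1 was the only one of the higher genes with a symbol, and FUT5, GALNT4 and ITGB3 were the lower ones with symbols. ITGB3 alone had whole counts, and its 2.03-fold difference from CON lies so close to the minimum of 2 that its call depends on the scaling. Of 32 lists, 5 were extreme on the low side against both CON and NT, with and without the GC and length trend. Random lists read in the same libraries gave 0.013 such lists, but their genes do not vary together as those of a real list do. The 5 lists were the mitochondrially encoded genes, epidermal differentiation genes, hypoxia and glycolysis genes, NRF2 targets and aryl hydrocarbon receptor targets. With the trend removed their medians against CON were -0.37, -0.24, -0.12, -0.10 and -0.12, and against NT -0.30, -0.24, -0.09, -0.08 and -0.13.

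CON against NT gives the difference between the libraries not given the inhibitor, as the background to the comparisons above. This background was larger than either of them. By the rule of size 222 genes differed, where GSK484 differed from CON in 62 and from NT in 71. The median absolute log2 fold of genes of at least 50 CPM was 0.12, against 0.08 and 0.09. EEA1, an early endosome tether gene, was at 2.54 CPM in CON and 7.97 in NT (log2 fold -1.65, interval -1.88 to -1.43). Mitosis genes had a median log2 fold of -0.22 (percentile 0), with 19 of 28 lower, among them CENPE (-1.26), CENPF (-1.23) and MKI67 (-0.75). SAMD9, an interferon-induced gene, was at -1.31, DST at -1.25, and POMK at -2.30. Ribosomal protein genes had a median of 0.20 (percentile 100), with 35 of 35 higher, and nuclear respiratory chain genes of 0.18 (percentile 99.99). Mitochondrially encoded genes had a median of 0.21 (percentile 99.93), with 12 of 13 higher.

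By the rule of size, 44 genes were higher and 178 lower in CON than in NT, of 13221, and the deposited TPM gave 115 higher and 232 lower. With the GC and length trend removed, 21 were higher and 44 lower, with genes of unknown GC content no longer counted. Across genes, the log2 fold correlated with GC content at r of 0.57 and with length at -0.44, and genes are not independent replicates. The same correlations were 0.61 and -0.35 for GSK484 against NT, and -0.32 and 0.34 for GSK484 against CON. Genes with divided reads and large folds were CXCR5, at least 320.1-fold higher in CON against a floor of 3 counts (interval bound of the log2 fold 8.02), GTF2IRD1P1, at least 25.4-fold higher (bound 4.35), ZBTB45P1, at least 32.1-fold lower (bound -4.67), GCOM1 (log2 fold 3.19), CDRT4 (1.61) and LYSMD3 (-2.49). Notch targets (0.22, percentile 99.55), epidermal differentiation genes (0.25, percentile 99.55), the PADI family (0.23, percentile 97.67) and antigen presentation genes (0.14, percentile 98.07) were extreme on the high side. Heat shock genes (-0.05, percentile 0.99) and basal genes (-0.05, percentile 0.53) were extreme on the low side. DNA replication genes had a median of 0.02 (percentile 27.4), with 10 higher and 10 lower of 26. With the trend removed, 6 of the extreme lists lay inside the central range, with medians of 0.01 for antigen presentation, -0.0050 for ribosomal, 0.03 for nuclear respiratory chain, 0.11 for Notch, 0.14 for epidermal and -0.01 for basal genes. Extreme values stayed for mitochondrially encoded genes (0.10, percentile 99.83), the PADI family (0.21, percentile 97.78), heat shock genes (-0.08, percentile 0.05) and mitosis genes (-0.07, percentile 0), and fatty acid synthesis genes became extreme (0.11, percentile 98.54). The log2 folds were then -0.80 for EEA1, -0.48 for CENPE, -0.90 for CENPF, -0.61 for SAMD9 and -0.86 for DST.

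**Figure D3:**
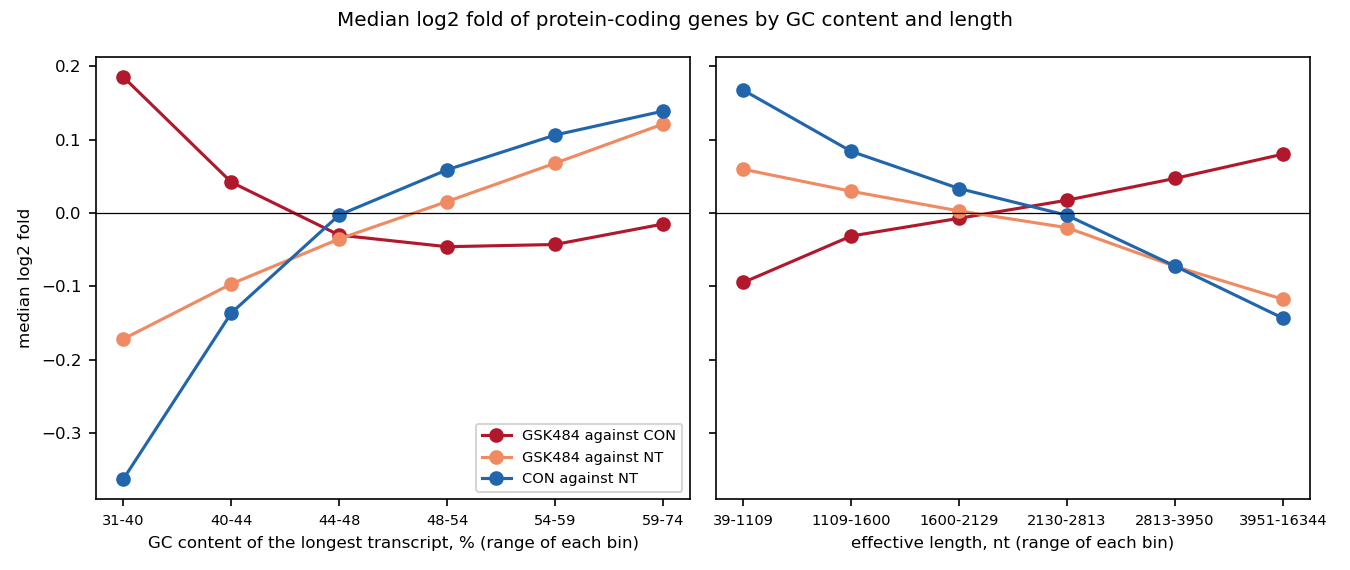
Lines give the median log2 fold of protein-coding genes in 6 equal bins of GC content in percent (left) and of effective length in nucleotides (right) for the 3 comparisons. In the lowest GC bin the medians were 0.19 for GSK484 against CON, -0.17 for GSK484 against NT and -0.36 for CON against NT.

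Both compounds were compared with the same NT library. Across 13312 genes, the log2 folds of GSK484 and CON over NT correlated at r of 0.68, where simulated libraries with no differences gave 0.55 from the shared library alone. The covariance was 0.093 against a simulated 0.0047, a difference of 0.088. With the GC and length trend removed, the covariance was 0.052, a difference of 0.047. In both compounds 19 genes were higher and 19 lower than in NT by the rule of size, where simulation gave 0 and independent lists 0.11 and 0.50. JMJD7, PVRIG2P and GCOM1 were among those higher, and POMK, ANKRD36BP1, SEPTIN7P13 and GALNT4 among those lower. The simulation held counting noise only, and the NT library cannot be split, so part or all of the excess may come from the NT library.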

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

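The settings named whole counts, GC and length trend removed, and without the CON library were chosen after the data were seen. With 1 library per group, no library of a group could be left out and no difference had a replicate check. No paired analysis was possible because each group has 1 library and no test was run. Gene counts are given in pairs, higher then lower. Where the count moved by over 1.5 times, the wider settings gave more genes by construction. The stricter settings, a CPM minimum of 5, a fold of 4 and whole counts alone, gave fewer genes by construction. With the trend removed, genes of unknown GC content could not be counted, which lowers those counts by construction. For the rest of such moves the cause was not tested. For GSK484 against CON (26 and 36), the deposited TPM without the counting interval gave 99 and 96, no CPM minimum 538 and 550, a CPM minimum of 5 gave 5 and 7, a fold of 1.5 gave 302 and 166, and a fold of 4 gave 4 and 6. Whole counts alone gave 6 and 7, and with the GC and length trend also removed 2 and 8. Without the CON library, with NT as the reference, the counts were 34 and 37, and with whole counts alone 6 and 10. For GSK484 against NT (34 and 37), TPM gave 110 and 138, no CPM minimum 484 and 569, a CPM minimum of 5 gave 5 and 8, a fold of 1.5 gave 181 and 216, and a fold of 4 gave 6 and 12. Whole counts alone gave 6 and 10, the trend removed gave 21 higher, and both together 2 and 13. For CON against NT (44 and 178), TPM gave 115 higher, no CPM minimum 535 and 789, a CPM minimum of 5 gave 6 and 118, a fold of 1.5 gave 230 and 850, and a fold of 4 gave 9 and 15. Whole counts alone gave 9 higher, the trend removed 21 and 44, and both together 4 and 15. In all, 43 gene counts stayed within 1.5 times. They include the 34 and 37 with NT as the reference, which are the counts of GSK484 against NT. Only 4 higher and 7 lower genes were shared with GSK484 against CON, so similar counts there do not mean that the same genes were kept. The correlation across genes of GSK484 and CON over NT was 0.684 with total counts, 0.683 with DESeq2 size factors, 0.654 with TPM, 0.689 with totals lacking short, mitochondrial and histone genes, 0.692 with a prior count of 5, 0.557 with no CPM minimum, 0.760 with a CPM minimum of 5 and 0.624 with the trend removed. Of the list medians extreme as scaled, 6 turned to 0 or the other sign, as did 92 values for lists inside the central range, whose scaled medians were typically 0.03 and at most 0.16 from 0. Of the 6, with no CPM minimum, breast stem cell markers for GSK484 against CON and epidermal differentiation genes for CON against NT had a median of 0, as genes near a count of 0 entered. With TPM, NRF2 targets (0.0056) and immediate early genes (0.041) for GSK484 against CON were above 0, where all measured genes had a median of 0.09. Relative to that median they were at -0.09 and -0.05. With the trend removed, ribosomal protein genes were at 0.0063 for GSK484 against CON and -0.0050 for CON against NT. Of all list medians under these settings apart from the 6, and so with the 92 included, 567 stayed within their counting interval and 195 moved beyond it. Of the folds of named genes, 2196 stayed within it and 630 moved. Genes below about 1 CPM, among them PADI4 and SOX2, rest on few counts.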

Other observations

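Among the genes of the preset lists, several lay on the same side of both other libraries in GSK484, beyond counting error each time. Higher were SNAI2 (log2 fold 0.42 against CON and 0.53 against NT), BCL11A (0.41 and 0.54), the metallothionein gene MT2A with divided reads (0.37 and 0.40), the receptor kinase gene AXL (0.33 and 0.28), LTBP2 with divided reads (0.35 and 0.30) and BMP4 (0.43 and 0.40). Lower were the transcription factor genes ATF3 (-0.61 and -0.73) and ID2 (-0.68 and -0.48), the phosphatase gene DUSP1 (-0.48 and -0.53), IGFBP3 (-0.54 and -0.40), FOXA1 (-0.28 and -0.23), the sterol reductase gene DHCR7 (-0.26 and -0.28), the WNT antagonist gene DKK1 (-0.23 and -0.29), VLDLR (-0.39 and -0.44) and CD14 (-0.55 and -0.32). Both values of each gene rest on the same GSK484 library, and these genes were picked here after their values were seen.

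In the patterns that follow, the tests of the GC and length trend on CON against NT, of shared reads, and of the mitochondrial genes against NT were chosen after the result was seen. Long, AT-rich transcripts were lower in CON than in NT. After a smooth trend on GC content and length was removed, 44 genes were lower by the rule of size in place of 178. The trend was fitted to these same folds, and genes of unknown GC content could no longer be counted, so a smaller count was to be foreseen. A library-wide trend, as RNA quality or library preparation could give, stays a candidate explanation, which this fall cannot tell from a biological one. The mitosis list kept a median below all random lists after the correction (percentile 0, median -0.07 against -0.22 before), while DNA replication genes had a median of 0.02 (percentile 53.65), so whether fewer cells were dividing in the CON culture was left open. With 1 library, an effect of the control compound and a difference of preparation were not separable.

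Genes past the rule of size for GSK484 against CON often had divided reads. Of the 62 genes, 20.97% had whole counts, against 54.8% in random gene sets matched on expression (central range 41.9% to 66.1%). Opposite signs in overlapping pairs such as MYZAP and GCOM1 go the same way. Reads moving between overlapping or near-identical genes may therefore give part of the 2-fold list. LOXL4, NDUFA4L2 and ITGB3 had whole counts, which show no division of reads but do not exclude it.

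Mitochondrially encoded transcripts were lower in GSK484 than in CON. The GC and length trend is argued against as the whole cause, since the median after its removal was -0.37 in place of -0.54. A higher level in CON alone is also argued against, since the median against NT was -0.29. Nuclear respiratory chain genes were lower against CON (median -0.11, percentile 0) but not against NT (median 0.06, percentile 89.8), so a joint fall against both libraries is argued against. With the trend removed their percentiles were 39.2 and 69.1. The trend was fitted to these same folds and may have taken out part of a fall. These percentiles therefore decide nothing, and a joint fall against CON alone is left open. An effect of GSK484 on mitochondrial RNA stays open as a hypothesis beside RNA recovery or handling of the single GSK484 culture, which could not be tested here.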
